A study of Mus musculus with 4 samples.

How the data were processed

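Single-cell RNA sequencing (10x 3' chemistry, version 3 per the labels' protocols) was run on mononuclear cells of the mouse gastrocnemius muscle 14 days after hindlimb ischemia surgery. The 4 libraries were wild-type control limb, wild-type ischemic limb, TRAIL-EC knockout control limb and TRAIL-EC knockout ischemic limb. Per the labels, each library was 1 pool of cryopreserved suspensions from 4 mice, 2 of each sex. TRAIL is the product of Tnfsf10, and the knockout name and the series title place its loss in endothelial cells. The titles of both knockout samples begin with the word Wildtype before the genotype TrailEC-/-, and the genotype was followed here. Which exons were deleted is not given in the sources used here.

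The deposited values were whole-number UMI counts per gene and barcode, made with Cell Ranger 7.1.0 per the file headers. The genome build was mm10 per the submitters' processing notes. Whether intronic reads were counted, and how the strand was used, is not given in the sources used here. The files listed 32285 genes, of which 32235 were matched to a mouse annotation of mm10 for coordinates. The wild-type control, wild-type ischemic, knockout control and knockout ischemic libraries held 23603, 12863, 14090 and 20000 barcodes. Their totals were 188554109, 105888789, 108900573 and 133010306 UMIs. The lowest barcode had 2306 UMIs in the knockout ischemic library and 500 UMIs in each other library.

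Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs. In the order above, 17136, 12079, 11502 and 17541 barcodes were kept. The mitochondrial limit removed 6442, 542, 2463 and 2397 barcodes. Doublets were scored with Scrublet in each library. The automatic threshold called 0 barcodes in the knockout control library and 22 in the knockout ischemic library. A fixed score of 0.25 was therefore used in every library, chosen after the data were seen. It removed 700, 528, 394 and 724 barcodes.

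Counts were normalised per cell and log-transformed with scanpy 1.11.5. The 2000 most variable genes gave 30 principal components and a graph of 20 nearest neighbours. Leiden clustering (leidenalg 0.10.2) at resolution 1 over all 4 libraries, without batch integration, gave 43 clusters. A cluster was named after a cell class, as endothelial-like for instance, by fixed markers of 17 classes. The naming thresholds were set after the data were seen. The mean scaled marker level had to reach 1, with at least 3 markers over 1 and a lead of 0.25 over the next class. It could hold no more markers of another class than of its own among its 10 leading genes, and a shallow cluster needed at least 1 of its own there. A cluster of 427 cells led by T or NK cell and mast cell genes was left unnamed for this reason, so T and NK cells are not analysed here. That cluster was counted among the background-rich clusters defined below. So was a cluster of 332 cells with the cycling genes Top2a, Mki67 and Cenpf among its leading genes. A cluster was not named either when its median UMI count passed 4 times the library's. Clusters were set aside as background-rich when they held fibroblast markers and endothelial markers together, each at 10% or more of its level in that class. Erythroid-, B- and myofibre-like clusters kept their name because no cleaner cluster of the class was found. The background-rich clusters took 4746, 995, 2121 and 9326 barcodes, or 28.9%, 8.61%, 19.1% and 55.5% of the cells of each library in the order above. Pericyte-like and smooth-muscle-like cells together are called mural. Gene and list values of pericyte-like cells include a mixed cluster of 1244 cells, with endothelial markers at 68.1% of the endothelial-like level. They therefore do not describe pericytes apart from endothelial transcripts.

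Summed UMIs per class and library were scaled to CPM, which gives every sum the same total. Log2 ratios used a pseudocount of 1 CPM and genes at 20 CPM or more in either library. Genes at least 2-fold apart were counted as a description of size. TMM factors came from edgeR 4.0.16 in R 4.3.3. A group's CPM had an exact Poisson interval, a share an exact binomial (Clopper-Pearson) interval and a ratio of sums an exact conditional interval, all at 95%. These intervals cover counting error only. Each group was 1 library, so no test between groups, p-value or standard error was computed, and cells were not treated as replicates. For each gene list and marker list, the median log2 ratio was ranked among 10000 random lists of the same size matched on mean expression in 10 bins. That percentile describes these libraries and is not a test. The code was tested on simulated counts without a true change, with 6572, 6635, 6664 and 6522 genes for the 4 comparisons in the order of the report, and it found 0 genes at 2-fold. With 100 genes changed 2.5-fold and 100 changed 4-fold, 100% were recovered in each comparison. The simulated counts were Poisson draws from 1 shared profile, without differences between pools or in cell mix. Changes were planted only in genes at 2 times the floor of 20 CPM or more. The simulation thus checks the code and says nothing on false calls between pools.

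The named genes were the 10 highest and the 10 lowest log2 ratios in endothelial-like cells of each comparison, and 5 and 5 in fibroblast-, pericyte-, macrophage- and myogenic-like cells. A named gene had to keep its direction, and at least 50% of its log2 size, both in cells with Xist and without Y-linked UMIs and in cells with Y-linked UMIs and without Xist. Mitochondrial, ribosomal protein, haemoglobin, sex-linked marker and unnamed gene models were left out. The members of each list with the largest ratios, and Tnfsf10, Tnfrsf10b, Cdh5 and Pecam1, were named as well. The comparisons, gene lists, markers, this rule and 14 of the alternatives were written before the data were examined. A further 8 alternatives were chosen after the data were seen. Reads, alignment and the barcodes that the submitters' cell calling discarded were not analysed here.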

Results

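Mononuclear cells of the gastrocnemius, a calf muscle, were profiled by single-cell RNA sequencing 14 days after surgery that restricts blood flow to 1 hindlimb. The series asks what TRAIL made by endothelial cells does in ischemic muscle, and its title names stable microvessels and the receptor TRAIL-R2. The 4 libraries crossed genotype with limb, and each was 1 pool of 4 mice, 2 of each sex. The mix of the sexes differed between the libraries all the same. Of the cells that could be told, 60.1%, 36.1%, 69.7% and 60.6% had Xist alone, in the order wild-type control, wild-type ischemic, knockout control and knockout ischemic, and 41.4%, 30.4%, 67.5% and 53.55% of the endothelial-like cells. There was no replicate of any group, and none of the differences given here has a replicate check. After filtering and removal of doublet calls, 16436 cells of the wild-type control limb, 11551 of the wild-type ischemic limb, 11108 of the knockout control limb and 16817 of the knockout ischemic limb remained. The median UMI count of the barcodes kept was 7681.5, 6848, 6906.5 and 4195 in that order.

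Endothelial-, fibroblast-, macrophage-, pericyte-, smooth-muscle-, tenocyte-, myogenic-, glial- and erythroid-like cells were found in every library. Fibroblast-like cells made up 26.6%, 24.2%, 23.8% and 17.0% of the cells in the order above. Macrophage-like cells made up 6.50%, 6.76%, 4.82% and 3.19%, and myogenic-like cells, marked by Pax7 and Calcr, 3.38%, 5.63%, 4.85% and 2.82%. Erythroid-like cells stood at 8.15%, 8.54%, 6.90% and 0.488%. Those cells have few UMIs, and the barcodes of the knockout ischemic library start at 2306 UMIs. With at least 2500 UMIs in every library the erythroid-like shares were 0.604%, 1.29%, 0.706% and 0.448%. Clusters holding fibroblast and endothelial transcripts together were set aside, and they took 28.9%, 8.61%, 19.1% and 55.5% of the cells, which lowers every other share.

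**Figure D1:**
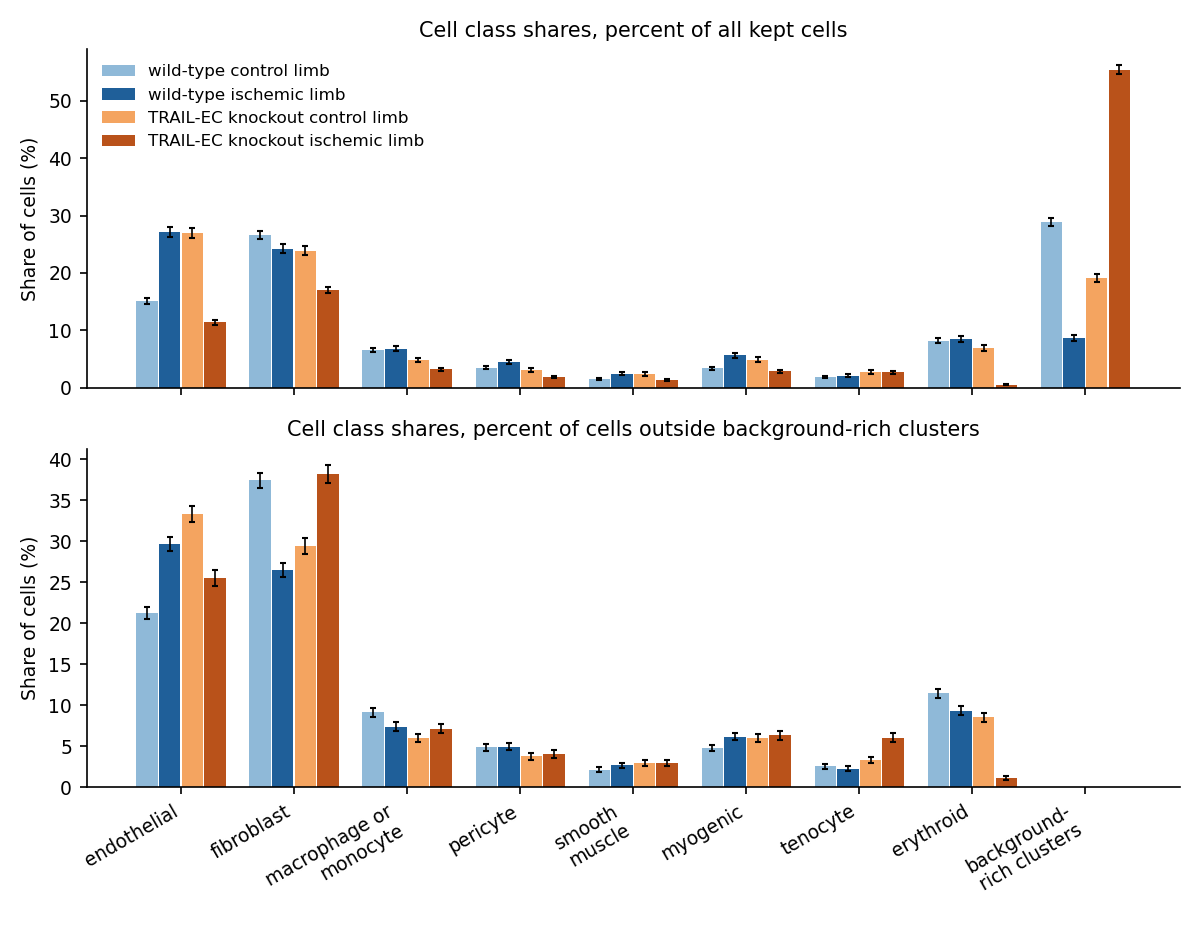
Share of cells (%) in each cell class for the 4 libraries, of all kept cells (top) and of cells outside the background-rich clusters (bottom), as bars with exact 95% binomial intervals for counting error. The background-rich clusters held 55.5% of the knockout ischemic library, and the endothelial-like share there was 11.4% of all cells and 25.6% of the cells outside those clusters.

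The targeted gene was examined first. Tnfsf10, which encodes TRAIL, lies on chromosome 3 at 27317028 to 27342427 (mm10, plus strand). In endothelial-like cells it stood at 87.1 CPM (95% counting interval 83.5 to 90.9) in the wild-type control limb and 58.9 CPM (56.0 to 62.0) in the knockout control limb, a ratio of 0.676 (0.632 to 0.723). In the ischemic limb it stood at 73.1 CPM (69.5 to 76.9) in wild type and 57.4 CPM (53.8 to 61.1) in the knockout, a ratio of 0.785 (0.723 to 0.851). Tnfsf10 transcripts thus remained in the knockout libraries at more than 50% of the wild-type level. The lower level in the knockout was found in cells of both sexes. Cells with Xist and without Y-linked UMIs had 96.1 and 62.4 CPM in the control limbs, and cells with Y-linked UMIs and without Xist had 87.3 and 55.2 CPM. Fibroblast-like cells had 2.19, 2.20, 2.40 and 2.21 CPM in the 4 libraries, so the endothelial level lay far above that background.

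Counted per cell, 46.2%, 33.4%, 32.4% and 32.4% of endothelial-like cells had a Tnfsf10 UMI, at median depths of 7947, 5289, 6716 and 6751.5 UMIs. In fibroblast-like cells the shares were 3.04%, 2.18%, 2.87% and 2.38% at 16002, 10436, 14570 and 12958 UMIs. After each cell was thinned to 1000 UMIs, the endothelial-like shares were 7.72%, 7.07%, 5.14% and 5.64%, with 19, 34, 40 and 0 shallower cells left out. The fibroblast-like shares were then 0.208%, 0.252%, 0.384% and 0.210%. Tnfrsf10b, the mouse TRAIL receptor gene on chromosome 14 at 69767472 to 69784411 (plus strand), stood at 21.2, 18.7, 17.0 and 16.0 CPM in endothelial-like cells. Its ratio of knockout over wild type was 0.803 (0.705 to 0.914) in the control limb and 0.858 (0.732 to 1.004) in the ischemic limb. Reads of this chemistry come mostly from the 3' end of a transcript, and the deleted part of Tnfsf10 is not given in the sources used here. A 3' tag outside the deleted part says nothing about whether the gene still makes protein, so these levels do not settle the genotype of the libraries.

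**Figure D2:**
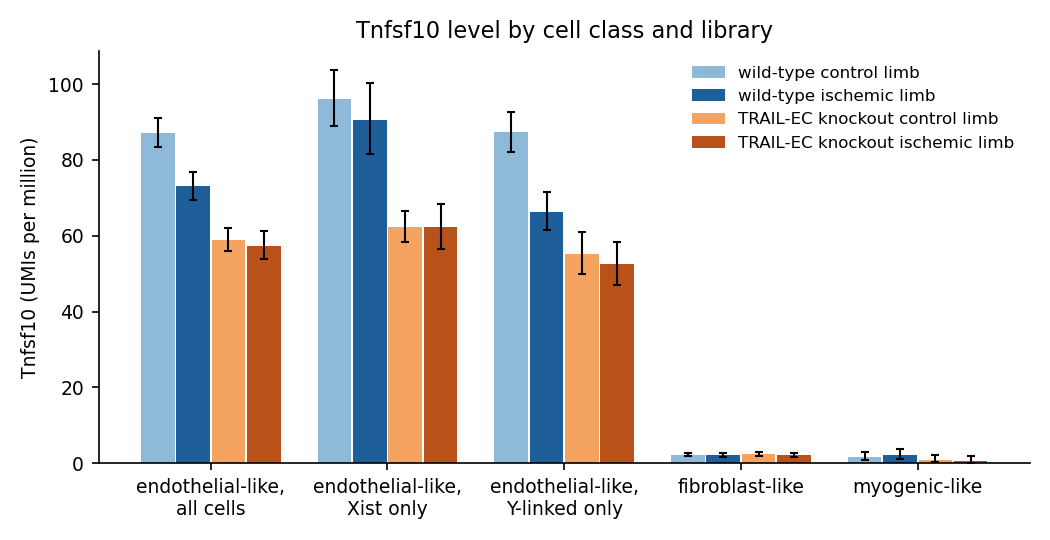
Tnfsf10 level (CPM) in endothelial-like cells, in endothelial-like cells of each sex, and in fibroblast- and myogenic-like cells of the 4 libraries, as bars with exact 95% Poisson intervals for counting error. Endothelial-like cells had 87.1 CPM in the wild-type and 58.9 CPM in the knockout control limb, against 2.19 and 2.40 CPM in fibroblast-like cells.

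The first comparison, ischemic over control limb in wild type, asks how the muscle differed 14 days after ischemia in wild type. Macrophage-like cells carried a strong repair signature, with Spp1 (osteopontin) at 669 against 4.65 CPM and Gpnmb at 98.2 against 3.86 CPM. Endothelial-like cells had higher glycolysis and oxidative phosphorylation genes, and higher Lrg1, a secreted modulator of TGF-beta signalling in vessels. The same library had the nuclear RNA Malat1 at 11898 against 21892 CPM over all barcodes of 2500 UMIs or more, and a median mitochondrial share of 4.28% against 6.48%. The endothelial-like share of cells was 27.1% (26.3 to 27.9) against 15.1% (14.5 to 15.7), a log2 ratio of 0.85 (0.77 to 0.92). Outside the background-rich clusters it was 29.7% against 21.2%, a log2 ratio of 0.48, and in cells with Y-linked UMIs alone the log2 ratio was 0.26. There were 25.7 mural cells per 100 endothelial-like cells in the ischemic limb and 33.0 in the control limb, a log2 ratio of -0.36 (-0.53 to -0.20). Without a pericyte-like cluster that also held endothelial transcripts, that log2 ratio was -0.11, and with a marker score per cell -1.05. Among endothelial-like cells, 76.5% and 75.1% were capillary-like, 15.4% and 16.9% arterial-like and 8.17% and 8.07% venous-like. Background-rich clusters with venous markers (21 and 322 cells) and with arterial markers (2 and 60 cells) were left out of these shares.

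Of 6818 endothelial genes, 8 were at least 2-fold higher and 48 at least 2-fold lower in the wild-type ischemic limb, of which 8 and 46 held in cells of both sexes. Over the alternatives the total of 56 ran from 26 to 197. Under CPM the median log2 ratio of all genes was -0.15 here, with a TMM factor of 0.926 for the ischemic library. With TMM factors the split was 16 higher and 22 lower. Lrg1 stood at 80.9 against 36.1 CPM, Gadd45g, a stress-response gene, at 155 against 74.4 CPM, and the immediate early gene Ier2 at 319 against 179 CPM. Gja4, which encodes an arterial gap junction protein, stood at 41.4 against 20.6 CPM. The contractile genes Acta2 and Tagln had log2 ratios of 1.02 and 0.87, the chemokine Pf4 0.81 and Selenoh 0.83. The Tagln difference was not found in the capillary-like cluster alone, at -0.04. Smooth muscle markers within endothelial-like cells stood at 229 against 193 CPM and macrophage markers at 140 against 106 CPM. AY036118 and Cmss1, at 1.02 and 0.93, were also among the 10 highest. Among the 10 lowest, Mdga2 had a log2 ratio of -2.19, Retnla -1.73, Pcdh7, a protocadherin, -1.55, and Chrm3, a muscarinic acetylcholine receptor, -1.52. The others were Nebl at -1.45, Zfpm2 at -1.33, Dlg2 at -1.31, Ptchd4 at -1.31, Adamts6 at -1.29 and Nckap5 at -1.27. Of the 10 highest genes 5, and of the 10 lowest 6, stood at under 20% of the level of their highest class. How far these ratios follow the lower share of nuclear RNA, seen in Malat1 of this library, was not tested. The endothelial markers Cdh5 and Pecam1 had log2 ratios of -0.14 and -0.13 under CPM and 0.01 and 0.02 with TMM factors.

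Among the gene lists in endothelial-like cells, glycolysis stood furthest apart. Its median log2 ratio was 0.60, at percentile 100 of matched random lists, and 7 of 12 members were at least 1.5-fold higher and none lower. Pkm, pyruvate kinase, stood at 184 against 99.3 CPM and Gapdh at 413 against 244 CPM, with Pfkl at 0.71 and Tpi1 at 0.70. Oxidative phosphorylation had a median of 0.43 (percentile 99.99) over 18 members, with Atp5g1 at 0.53 and Cox5a at 0.48. The endothelial-to-mesenchymal list had a median of 0.31 (percentile 98.35), with 3 of 8 members at least 1.5-fold higher, among them Vim at 0.88, and 2 lower, among them Zeb2 at -0.90. The repair macrophage list had a median of 0.42 (percentile 98.77) in endothelial-like cells, through Ctsd at 0.55 and Apoe at 0.53. The hypoxia list had a median of 0.04 (percentile 83.9), with Pgk1 at 0.69 and P4ha1 at -0.41. VEGF and angiopoietin genes had a median of -0.21 (percentile 35.9), with Vegfc at -0.55 and Nrp2 at -0.48. Mural recruitment genes had -0.24 (percentile 32.0), with Jag1 at -0.40 and Pdgfb at -0.26. TRAIL pathway genes had -0.26 (percentile 36.4), with Cflar at -0.37, Ripk1 at -0.35 and Tnfsf10 at -0.25. Junction genes had -0.12 (percentile 48.6), with Cldn5 at 0.48 and Tjp1 at -0.44. Of the p53 and apoptosis list, 1 of 11 members was at least 1.5-fold lower, the survival gene Bcl2 at -1.10.

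**Figure D3:**
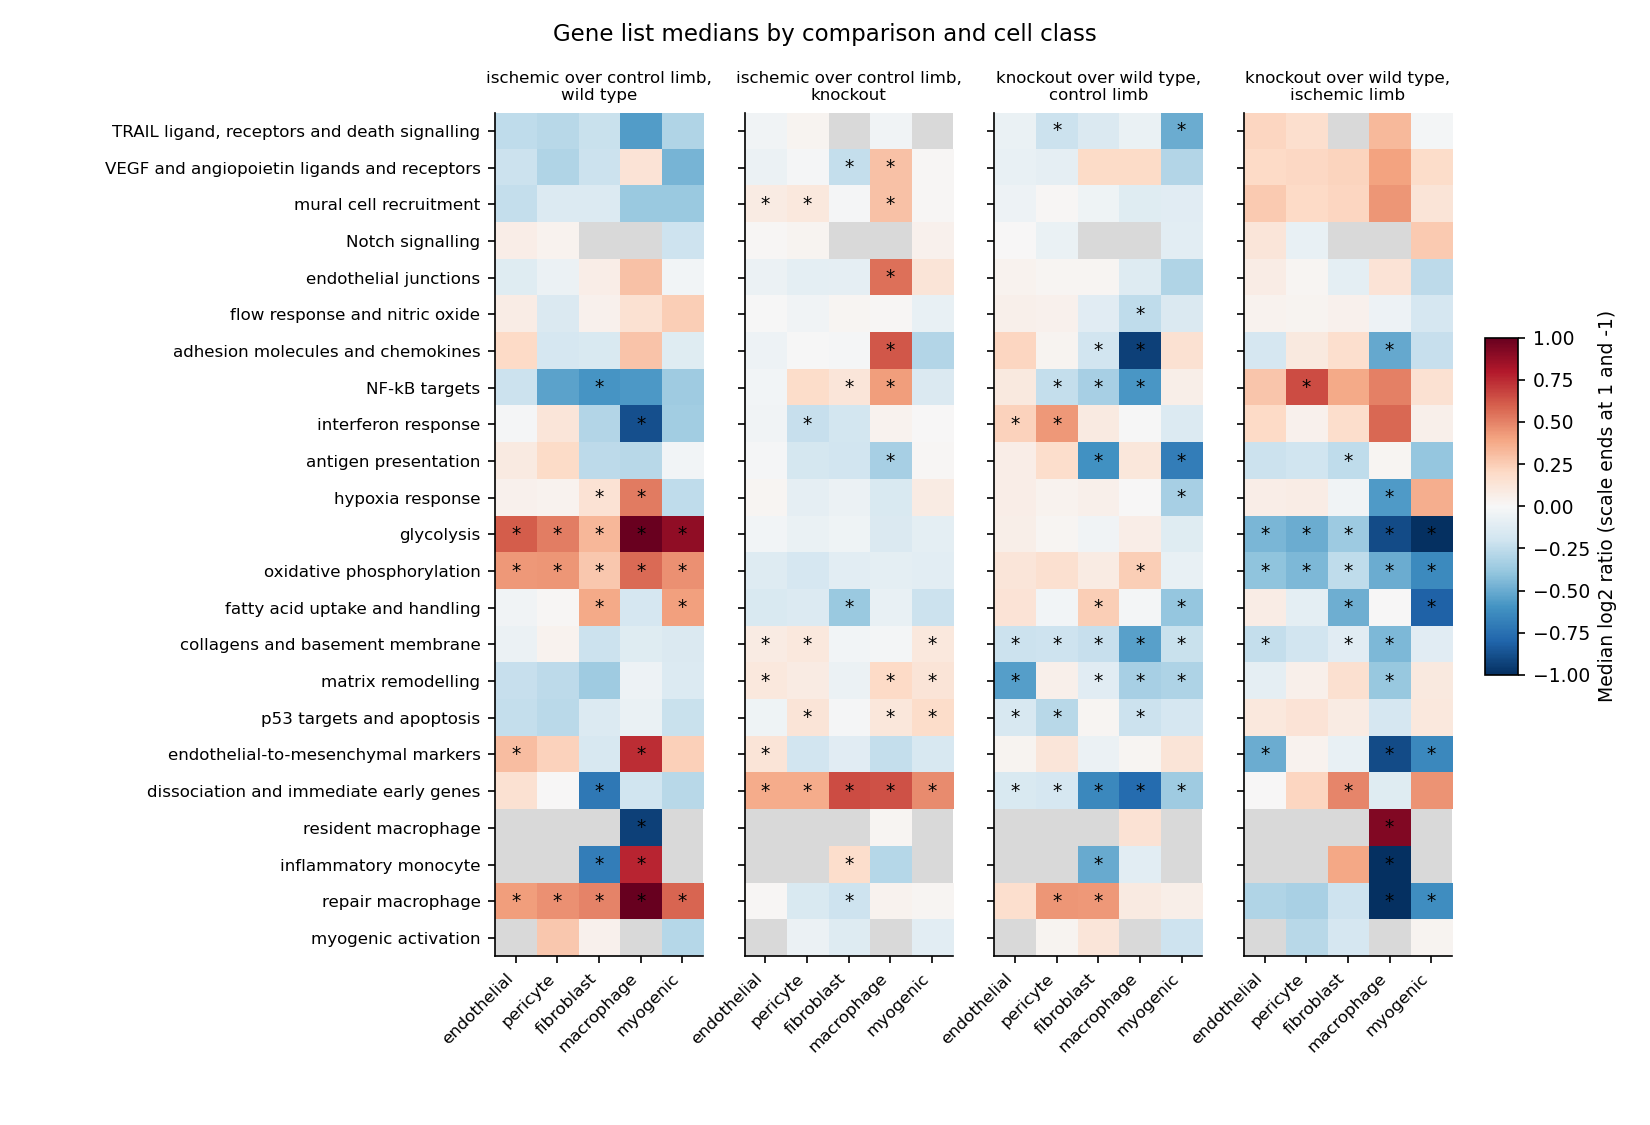
Median log2 ratio of 23 gene lists (vertical axis) in 5 cell classes (horizontal axis) for each of the 4 comparisons, as a colour scale that ends at 1 and -1, with grey where fewer than 3 members were measured and a star where the median lay beyond percentile 2.5 or 97.5 of matched random lists. Glycolysis was higher in the wild-type ischemic limb in all 5 classes, with medians from 0.33 in fibroblast-like to 0.99 in macrophage-like cells.

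Macrophage-like cells differed most between the wild-type limbs, with 122 genes at least 2-fold higher and 493 lower of 6742, of which 60 and 341 held in cells of both sexes. The repair list had a median of 2.35 (percentile 100), and 9 of 10 members were at least 1.5-fold higher and 1 lower. Trem2, a lipid receptor, stood at 520 against 77.2 CPM and Fabp5, a fatty acid carrier, at 569 against 51.6 CPM. AA467197 had a log2 ratio of 5.06, Syngr1 4.55, Sox4 2.59 and Tmem119 2.58. The inflammatory monocyte list had a median of 0.76 (percentile 99.96), with Thbs1 at 3.35 and Chil3 at 2.52. Within the 2 main macrophage-like clusters its median was -0.08 and 0.01, so the value of the class followed the mix of clusters. Glycolysis had 0.99 (percentile 100), with 10 of 13 members at least 1.5-fold higher, and hypoxia 0.52 (percentile 99.74). Resident macrophage genes had a median of -0.93 (percentile 0.490), with 5 of 9 members lower, among them the hyaluronan receptor Lyve1 at -1.28, the haemoglobin scavenger receptor Cd163 at -1.17 and Timd4 at -0.96. Interferon genes had a median of -0.88 (percentile 0.0800), with 7 of 11 lower, among them Ifit2 at -2.38 and Rsad2 at -1.96. Retnla stood at 1532 against 7560 CPM, and Thsd4 at -2.83, Cd226 at -2.42, Chn2 at -2.27 and Aff3 at -2.27 were the other 4 lowest. A background-rich cluster with Cd209f, F13a1 and Cd163, of 997 control and 173 ischemic cells, was left out of the class. In the class itself, a resident-type cluster, led by Cd209f, F13a1 and Folr2, held most macrophage-like cells of the control limb (752 cells, against 317 in a cluster led by Lyz1, Cxcl2, Trem2 and Ccr2), and the second cluster held most of the ischemic limb (411 against 370). The Spp1 log2 ratio was 2.86 in cells with Xist alone and 7.86 in cells with Y-linked UMIs alone, so cells of both sexes had it and to unequal extents. Within that second cluster the repair list still had a median of 2.88, while the resident list had 0.20 there and -0.21 in the resident-type cluster.

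**Figure D4:**
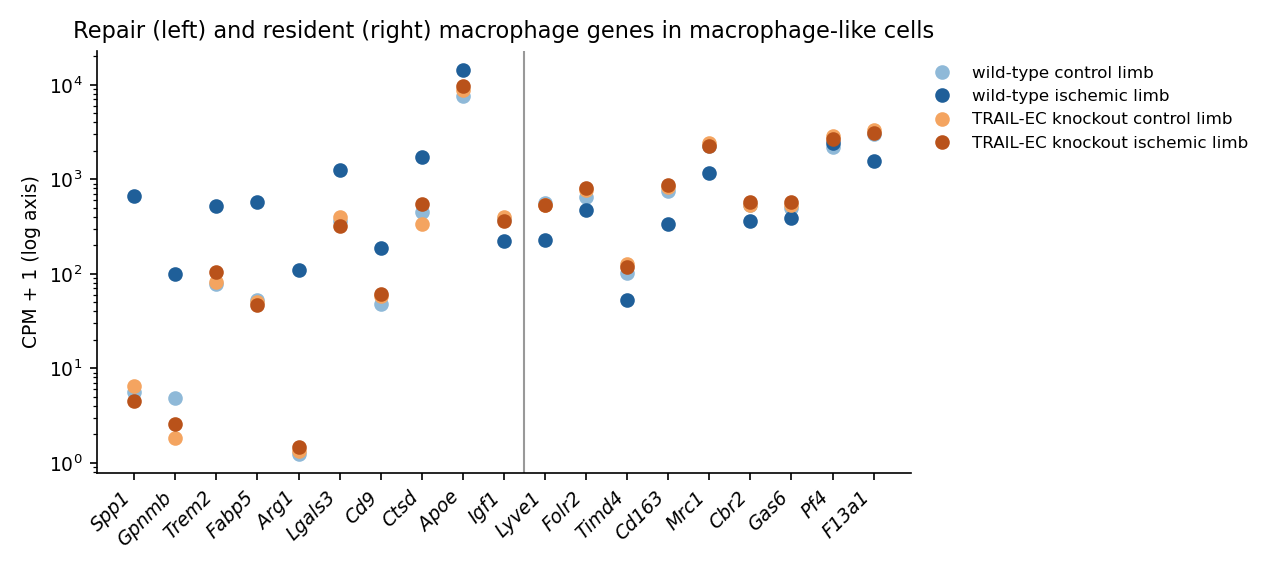
Level (CPM plus 1, log axis) of repair genes (left) and resident genes (right) in macrophage-like cells, with 1 point per library. Spp1 stood at 669 CPM in the wild-type ischemic limb and at 4.65 CPM or less in the wild-type control and knockout ischemic limbs.

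Other classes also differed between the wild-type limbs, with single genes in both directions. In fibroblast-like cells the matrix protein gene Comp stood at 127 against 33.9 CPM, with Mfap4 at 1.22, the chemokine Ccl19 at 1.20 and Gdf10 at 1.18. Ptx3 had a log2 ratio of -2.73, Slit2 -2.28, Ptgs2, the inducible cyclooxygenase, -2.07, Tnfaip6 -1.90 and Sema3a -1.75. Slit2 also led a fibroblast-like cluster with 216 cells of the control and 23 of the ischemic limb. A cluster led by Timp1, Tnc, Cthrc1 and Lox, of 10 control and 475 ischemic cells, scored highest for fibroblast markers. It missed the naming thresholds and was left out of the fibroblast-like class. The dissociation and immediate early list had a median of -0.71 (percentile 0) in fibroblast-like cells. In myogenic-like cells Lgals3 (galectin-3) stood at 113 against 10.1 CPM and Tnc (tenascin-C) at 25.2 against 2.32 CPM, with Cnn2 at 1.45 and Tpi1 at 118 against 49.0 CPM. Spon1 at -2.94, Frmd4b at -1.98 and the receptor gene Tshr at -1.80 were lower. Pericyte-like cells had Lyz2 at 1.17, Clu at 1.04 and Syt15 at 1.02, against Sox6 at -2.05 and Kcnab1 at -1.94, and a glycolysis median of 0.51 (percentile 100). Over all barcodes of 2500 UMIs or more, the regeneration-associated embryonic myosin gene Myh3 stood at 6.99 against 0.101 CPM, Tnnt2 at 28.8 against 0.679 CPM and Timp1 at 292 against 17.8 CPM. A cluster led by Tnnt2, Actc1, Myog and Myh3 held 153 cells, all from the wild-type ischemic library, and 1 library per group does not separate a cell type from a library.

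The second comparison, ischemic over control limb in the knockout, asks the same question in the mice labelled as knockout. Few endothelial genes were 2-fold apart, and the repair signature of macrophage-like cells was not higher. The dissociation and immediate early list, whose genes also respond to tissue handling, was higher in all 5 classes examined, with Hspa1b, an inducible heat shock protein gene, at 105 against 42.8 CPM and Fosb at 93.7 against 43.1 CPM in endothelial-like cells. The median mitochondrial share was 7.86% against 5.62%, and Malat1 over all barcodes of 2500 UMIs or more stood at 22996 against 30376 CPM. The endothelial-like share was 11.4% (10.9 to 11.9) against 27.0% (26.1 to 27.8), a log2 ratio of -1.24 (-1.33 to -1.16). Outside the background-rich clusters it was 25.6% against 33.3%, a log2 ratio of -0.38. Mural cells numbered 27.3 per 100 endothelial-like cells in the ischemic and 20.1 in the control limb, a log2 ratio of 0.45 (0.25 to 0.64), which was 1.26 with background-rich clusters counted in their class and 1.54 with a marker score per cell.

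Of 6700 endothelial genes, 17 were at least 2-fold higher and 8 lower in the knockout ischemic limb, and 17 and 7 with TMM factors. In cells of both sexes 14 of the higher and 0 of the lower genes held, and with a marker score per cell the split was 169 higher and 5 lower. AY036118 at 1.35 and Lars2 at 1.26 were among the 10 highest, with Ntm at 1.15, Pde1c at 1.10, Fndc1 at 1.07, Cytl1 at 1.05 and Smoc2 at 1.03. Of the 10 highest, 7 stood at under 20% of the level of their highest class. Ntm and Pde1c were also leading genes of the largest background-rich cluster, with 3970 cells in the ischemic and 861 in the control limb. The 10 lowest had smaller ratios, from Slfn3 at -0.86, Taco1 at -0.73 and the nuclear RNA Malat1 at -0.63 to Nop14 at -0.61, Prpf4b and Ramp3 at -0.59, and Msl3, Srr and Rnpc3 at -0.55. Car4, a capillary carbonic anhydrase gene, stood at 159 against 237 CPM. The dissociation and immediate early list had a median of 0.37 (percentile 100), with 4 of 16 members at least 1.5-fold higher, among them Hspa1a at 1.03 and Atf3 at 1.01. In cells with Y-linked UMIs alone that median was -0.17. Collagen and basement membrane genes had a median of 0.08 (percentile 100), with 4 of 19 members higher, among them Col6a3 at 0.77, Col1a1 at 0.71 and Col1a2 at 0.70. Matrix remodelling genes had 0.11 (percentile 98.7), with Timp2 at 0.61, and endothelial-to-mesenchymal markers 0.13 (percentile 99.88), with Acta2 at 0.40. Fibroblast markers within endothelial-like cells moved with these groups, at 1015 against 634 CPM. Mural recruitment genes had a median of 0.08 (percentile 99.64), with Hbegf at 0.28 and Jag1 at 0.22, and venous markers 0.21 (percentile 99.97), with Vwf at 0.44. The venous-like share of endothelial-like cells went the other way, at 6.17% against 9.25%, with the arterial-like share at 19.6% against 15.9%. These shares leave out the background-rich clusters. Angptl4, a lipase inhibitor induced by hypoxia and fatty acids, stood at 6.55 against 32.4 CPM, the chemokine Cxcl9 at -1.07 and the fatty acid regulator Pparg at -0.66. Endothelial-like cells of the knockout control limb held more adipocyte markers than those of the wild-type control limb, as given with the third comparison. How far the lower Angptl4 and Pparg follow such transcripts was not tested. Fatty acid handling genes had a median of -0.15 (percentile 4.22). Glycolysis had -0.03 (percentile 87.6), hypoxia 0.02 (percentile 96.4), VEGF and angiopoietin genes -0.06 (percentile 64.4) and TRAIL pathway genes -0.04 (percentile 74.7). Tnfsf10 was level between the knockout limbs, with a ratio of 0.974 (0.897 to 1.06).

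Macrophage-like cells of the knockout limbs had 36 genes at least 2-fold higher and 13 lower of 6761, of which 19 and 2 held in cells of both sexes. The neutrophil chemokine Cxcl1 stood at 42.5 against 8.03 CPM and Cxcl2 had a log2 ratio of 1.02. Ccrl2 at 1.63, Dmac2l at 1.69 and Polg2 at 1.61 were among the 5 highest, and Klra2 at -1.83, Cd226 at -1.16, Cd200r1 at -0.96, Rnase6 at -0.96 and Bcl2a1d at -0.96 were the 5 lowest. Dissociation and immediate early genes had a median of 0.63 (percentile 100; 10 of 16 members higher), adhesion molecules and chemokines 0.62 (percentile 100) and NF-kB targets 0.42 (percentile 100), with the NF-kB inhibitor gene Tnfaip3 at 1.17. Antigen presentation genes had -0.33 (percentile 0.0200), with the class II chaperone gene Cd74 at -0.49. The repair list had a median of 0.04 (percentile 85.0) and the resident list 0.02 (percentile 79.7). In fibroblast-like cells Ptgs2 stood at 51.5 against 16.0 CPM, the hyaluronan synthase gene Has1 at 1.39 and Fosb at 1.30, and the dissociation and immediate early list had a median of 0.65 (percentile 100). Hoxa9 at -0.95, Iigp1 at -0.90 and Mdk at -0.87 were lowest there. Pericyte-like cells had Fosb at 1.43 and Atf3 at 1.41, against the activin antagonist gene Fst at -1.66 and Angpt1, which encodes the ligand of the endothelial receptor Tek, at -0.93. Some limb differences were shared by the 2 genotypes. Pparg was lower in endothelial-like cells of both ischemic limbs, with -0.72 in wild type beside the -0.66 above. The limit given there, the adipocyte markers of the knockout control library, holds for the knockout value. The interferon-induced Iigp1 was lower in fibroblast-like cells, at -1.03 in wild type, and so was Slit2, at -3.06 in the knockout, although not in knockout cells with Y-linked UMIs alone, at -0.03. Erythroid markers within endothelial-like cells were at 2752 against 845 CPM in wild type and 3350 against 1603 CPM in the knockout. Within fibroblast-like cells they were at 560 against 85.5 and 909 against 326 CPM, but they were lower in the ischemic limb within myogenic-like cells, at 991 against 1717 and 104 against 220 CPM. They went opposite ways by genotype within macrophage-like cells, at 403 against 595 and 615 against 101 CPM, and within pericyte-like cells, at 1484 against 1599 and 2475 against 504 CPM.

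The third comparison, knockout over wild type in the control limb, asks how the 2 genotypes differed in the control limb. Endothelial-like cells of the knockout had lower Tnfsf10, higher interferon-induced genes and lower transcripts of collagens, together with lower fibroblast markers (634 against 1251 CPM). Cfd, the adipocyte-enriched complement gene adipsin, stood at 65.8 against 3.87 CPM, a ratio of 17.0 (13.8 to 21.1), and adipocyte markers within these cells stood at 12.3 against 1.11 CPM. The endothelial-like share was 27.0% against 15.1%, a log2 ratio of 0.84 (0.76 to 0.91), and 33.3% against 21.2% outside the background-rich clusters. In cells with Y-linked UMIs alone the log2 ratio was 0.33, and in cells with Xist alone 1.28. Mural cells numbered 20.1 against 33.0 per 100 endothelial-like cells, a log2 ratio of -0.72 (-0.89 to -0.55), or -0.34 without the pericyte-like cluster that held endothelial transcripts.

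Of 6757 endothelial genes, 12 were at least 2-fold higher and 28 lower in the knockout control limb, and 11 and 29 with TMM factors. In cells of both sexes 4 of the higher and 27 of the lower genes held. Next to Cfd, the 10 highest were Lhfpl3 at 1.19, Car4 at 237 against 128 CPM, H2-T24 at 0.80, Epb41l4aos at 0.77, Slfn2 at 0.71, Ifi202b at 0.69, Ifit3 at 44.4 against 27.3 CPM, the leptin receptor gene Lepr at 0.68 and Mgst1 at 0.64. Tpm3-rs7, which the naming rule did not pick, stood at 25.5 against 2.60 CPM. It was higher in the knockout in the ischemic limb as well, at 30.4 against 2.97 CPM. Interferon genes had a median of 0.23 (percentile 99.92) over 15 members, with Rsad2 at 0.53 and Isg15 at 0.30, and 1 member, Ifit3, at least 1.5-fold higher. Among the 10 lowest, Col1a2 stood at 63.4 against 148 CPM and Col1a1 at 44.2 against 101 CPM, with Col6a3 at -1.17, Col6a2 at -1.16 and Col6a1 at -1.13. Collagen and basement membrane genes had a median of -0.21 (percentile 0), with 8 of 19 members at least 1.5-fold lower and none higher. Matrix remodelling genes had -0.55 (percentile 0), with the protease gene Mmp2 at -0.78, its inhibitor Timp2 at -0.79 and Adamts1 at -0.55. Macrophage markers within endothelial-like cells were lower as well, at 48.1 against 106 CPM. The macrophage-enriched genes Retnla at -1.34, C1qa at -1.18 and H2-Eb1 at -1.15 were lower too, as were H2-Aa at -1.13 and Cd74 at -1.05 of the antigen presentation list, whose median was 0.07 (percentile 56.7). Of the 10 lowest genes, 9 stood in endothelial-like cells at under 20% of the level of their highest class. Hspa1b had a log2 ratio of -1.32 and Lars2 -1.19, and dissociation and immediate early genes a median of -0.16 (percentile 0), with Hspa1a at -0.97 and Atf3 at -0.86. The p53 and apoptosis list had -0.16 (percentile 0.0500), with Cdkn1a at -0.32. In cells with Y-linked UMIs alone both medians were positive, at 0.49 and 0.28. VEGF and angiopoietin genes had a median of -0.07 (percentile 2.57), with Angptl4 at 1.13 and Flt4 at -0.23, and arterial markers -0.11 (percentile 2.32), with Fbln5 at -0.48 and Gja5 at -0.34. TRAIL pathway genes had -0.07 (percentile 6.69) and mural recruitment genes -0.05 (percentile 6.52), with Hbegf at -0.47.

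Macrophage-like cells of the knockout control limb had 8 genes at least 2-fold higher and 67 lower of 6778, of which 3 and 22 held in cells of both sexes. Adhesion molecules and chemokines had a median of -0.93 (percentile 0; 6 of 7 members lower), NF-kB targets -0.58 (percentile 0) and dissociation and immediate early genes -0.77 (percentile 0; 11 of 16 lower). The anti-inflammatory cytokine gene Il10 stood at 2.51 against 21.5 CPM, with Nr4a3 at -2.17, Nfil3 at -2.11, Cxcl1 at -2.03, Polg2 at -1.73 and Tnfaip3 at -1.85. Ddb2 at 1.24, Barx2 at 1.09 and the flagellin receptor gene Tlr5 at 0.97 were highest. Fibroblast-like cells had Apoe at 634 against 300 CPM, and Ptgs2 at -2.20, Ptx3 at -2.15, Has1 at -2.00 and Fosb at -1.40. Pericyte-like cells had Mgst1 at 71.8 against 24.8 CPM, Fst at 1.37 and Angpt1 at 21.2 against 8.38 CPM, and an interferon median of 0.44 (percentile 100). Myogenic-like cells had the muscle spring gene Ttn at -3.47 and the protease gene Adam12 at -2.35, against Rcan2 at 1.48.

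The fourth comparison, knockout over wild type in the ischemic limb, asks how the 2 genotypes differed in the ischemic limb. Each library enters 2 of the 4 comparisons, and the wild-type ischemic library enters this one and the first, so a value particular to that library moves both. Macrophage-like cells of the knockout had 3.50 CPM of Spp1 against 669 CPM and 1.59 CPM of Gpnmb against 98.2 CPM. Endothelial-like cells had lower glycolysis genes, lower Lrg1 (40.3 against 80.9 CPM) and lower Postn (periostin, 4.28 against 21.2 CPM). The endothelial-like share was 11.4% against 27.1%, a log2 ratio of -1.253 (-1.34 to -1.17), and 25.6% against 29.7% outside the background-rich clusters, a log2 ratio of -0.22. Mural cells per 100 endothelial-like cells, at 27.3 and 25.7, had a log2 ratio of 0.09 (-0.09 to 0.27), which was 1.01 with background-rich clusters counted in their class and 1.59 with a marker score per cell, but -0.10 in cells with Xist alone and -0.14 at Leiden resolution 0.5. The capillary-, arterial- and venous-like shares of endothelial-like cells were 74.2%, 19.6% and 6.17% in the knockout. A background-rich cluster with the venous markers Selp, Lrg1 and Vwf held 696 cells in the knockout and 21 in wild type. Another with the arterial markers Bmx, Gja5 and Sema3g held 243 and 2 cells. Both were left out of these shares, which therefore depend on what was set aside.

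Of 6734 endothelial genes, 42 were at least 2-fold higher and 5 lower in the knockout ischemic limb, of which 38 and 4 held in cells of both sexes. With a marker score per cell the split was 198 higher and 6 lower. Under CPM the median log2 ratio of all genes was 0.10, and with TMM factors the split was 27 higher and 15 lower. The 10 highest were Pcdh7 (36.0 against 9.33 CPM), Chrm3 (65.9 against 20.0 CPM), Ptchd4 at 1.38, the CREB-family factor gene Creb5 at 1.37, Zfpm2 at 1.33, Grik1 at 1.33, the cGMP-dependent kinase gene Prkg1 at 1.29, Celf2 at 1.29, Xlr5a at 1.29 and Arhgap24 at 1.27. Of these 10, 9 stood at under 20% of the level of their highest class. Malat1 stood at 22996 CPM in the knockout and 11898 CPM in the wild-type ischemic library. How far the ratios of these 10 genes follow that difference was not tested. Grik1 and Xlr5a were also leading genes of the largest background-rich cluster, with 3970 cells in the knockout and 410 in wild type. Tpm3-rs7, which the naming rule did not pick, stood at 30.4 against 2.97 CPM. The lowest besides Postn and Lrg1 were Tmem252 at -1.41, Lyz2 at -1.05, S100a4 (21.2 against 43.4 CPM), Lgals1 at -0.96, the interleukin-31 receptor gene Il31ra at -0.95, C1qb at -0.95, Pf4 at -0.94 and Cmss1 at -0.89. Of the 10 lowest, 7 stood at under 20% of the level of their highest class. Macrophage markers within endothelial-like cells stood at 79.7 against 140 CPM, and fibroblast markers at 1015 against 1066 CPM. Glycolysis genes had a median of -0.46 (percentile 0), with 3 of 12 members at least 1.5-fold lower, Pkm at -0.79, Gapdh at -0.73 and Pgk1 at -0.72. Oxidative phosphorylation had -0.40 (percentile 0), with Atp5g1 at -0.63. Endothelial-to-mesenchymal markers had -0.50 (percentile 0), with 4 of 8 members lower, among them Vim at -0.92 and Acta2 at -0.88, and 1 higher. Collagen and basement membrane genes had -0.24 (percentile 0.210), with Col18a1 at -1.13 and Sparc at -0.54, and venous markers -0.32 (percentile 2.29). VEGF and angiopoietin genes had 0.20 (percentile 68.8), with Vegfc at 0.41 and Nrp2 at 0.33, mural recruitment genes 0.27 (percentile 80.0), with Jag1 at 0.35, and TRAIL pathway genes 0.22 (percentile 60.0), with Ripk1 at 0.28. Interferon genes had 0.20 (percentile 70.2), with Ifit2 at 0.75. The shear-responsive factor gene Klf4 had 0.64 and Bcl2 0.87.

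Macrophage-like cells of the ischemic limbs had 314 genes at least 2-fold higher and 131 lower in the knockout, of 6704, and 225 and 83 of them held in cells of both sexes. The repair list had a median of -2.15 (percentile 0), with 8 of 10 members at least 1.5-fold lower and 1 higher, and Fabp5 at -3.59. AA467197 at -4.74 and Syngr1 at -4.44 were among the 5 lowest, and Timp1, with 2 UMIs in the knockout, had a ratio of 0.0126 (0.00152 to 0.0461). Inflammatory monocyte genes had -1.56 (percentile 0), with Thbs1 at -4.02, and glycolysis -0.89 (percentile 0; 10 of 13 lower). Resident macrophage genes had 0.92 (percentile 99.9; 7 of 9 higher), with Cd163 at 1.38, Lyve1 at 1.23 and Timd4 at 1.16. Oasl1 at 2.37, Negr1 at 2.16, Mctp2 at 1.87, Aff3 at 1.87 and the chemokine Ccl8 (1622 against 456 CPM) were the 5 highest. A background-rich cluster with resident-type genes, of 1238 cells in the knockout and 173 in wild type, was left out of the class. The resident-type cluster held 406 of the macrophage-like cells of the knockout and the other cluster 130. Within that other cluster the repair median was -2.83 (percentile 0), and within the resident-type cluster -0.20 (percentile 0.890). The resident list had 0.10 in the resident-type and -0.12 in the other cluster (percentiles 47.1 and 25.2), and the inflammatory list 0.06 and -0.17, so these differences of the class followed the mix of clusters. Myogenic-like cells of the knockout had lower Lgals3 at -4.51, lower Myog, the differentiation factor myogenin, at 3.79 against 90.6 CPM, and lower Tnc at -3.97, S100a4 at -2.59 and Postn at -2.56, against higher Rcan2 at 1.87. Myog was not particular to the ischemic limb, with 253 CPM in myogenic-like cells of the wild-type control limb. Fibroblast-like cells had Timp1 at -1.57 and S1pr3 at -1.14, while Ptgs2 stood at 51.5 against 17.5 CPM and Atf3 at 1.43. The class leaves out the unnamed cluster led by Timp1, Tnc, Cthrc1 and Lox, of 6 knockout and 475 wild-type cells. Pericyte-like cells had Sox6 at 2.02 and Atf3 at 1.74, and a glycolysis median of -0.50 (percentile 0).

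Several lists stayed within percentiles 2.5 and 97.5 in endothelial-like cells in all 4 comparisons. These were the TRAIL, VEGF and angiopoietin, Notch, junction, flow and nitric oxide, adhesion, NF-kB, antigen presentation, hypoxia and fatty acid lists. The Notch medians were 0.07, 0.01, 0.00 and 0.12 in the order of the comparisons, the flow and nitric oxide medians 0.07, -0.01, 0.05 and 0.04, and the adhesion medians 0.20, -0.05, 0.22 and -0.17. NF-kB targets had -0.21, -0.03, 0.10 and 0.28, and tip-like endothelial markers -0.17, 0.08, -0.04 and 0.02. Of the 24 genes named for endothelial-like cells in each comparison, 2, 2, 1 and 3 overlap another gene on the same strand and 8, 9, 5 and 8 one on the opposite strand. Their counts cannot be told from those of the overlapping gene with the sources used here.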

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

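The results in this part were found by comparing the limb ratios of the 2 genotypes, and none of the differences was tested. Of the tests reported here, only the count of barcodes with transcripts of both sexes was chosen before its result was seen.

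The log2 ratio of ischemic over control limb went clearly opposite ways in the 2 genotypes for 18 results, given here as knockout minus wild type. A share or mural ratio counted when both intervals excluded 0, a named gene when both ratios were at least 2-fold, and a list when its medians lay beyond percentiles 2.5 and 97.5 on opposite sides. Smaller differences of sign, such as glycolysis in endothelial-like cells (0.60 and -0.03), are not listed. The endothelial-like share differed by -2.09 (-1.24 against 0.85), and mural cells per 100 endothelial-like cells by 0.81 (0.45 against -0.36). The mural difference did not pass this rule under 3 of the alternatives. The wild-type ratio was -0.11 (-0.32 to 0.10) without the mixed pericyte-like cluster, -0.29 (-0.61 to 0.03) with Xist alone and -0.22 (-0.46 to 0.03) with Y-linked UMIs alone, where the knockout had 0.31 (-0.03 to 0.66). In endothelial-like cells Pcdh7 differed by 2.57 (1.02 against -1.55), Arhgap24 by 2.35 (1.31 against -1.04) and Ntm by 2.25 (1.15 against -1.10). In fibroblast-like cells Ptgs2 differed by 3.70 (1.63 against -2.07) and Has1 by 2.99 (1.39 against -1.60). Fibroblast-like list medians differed by 1.36 for dissociation and immediate early genes (0.65 against -0.71), 0.71 for NF-kB targets (0.12 against -0.59) and 0.87 for inflammatory monocyte genes (0.18 against -0.69). They differed by -0.75 for fatty acid handling (-0.37 against 0.38), -0.70 for repair macrophage genes (-0.21 against 0.49) and -0.91 for capillary endothelial markers (-0.31 against 0.60). Within fibroblast-like cells, endothelial markers stood at 242 against 189 CPM in the wild-type and 178 against 183 CPM in the knockout limbs, and macrophage markers at 120 against 83.9 and 65.4 against 38.7 CPM. In pericyte-like cells Atf3 differed by 2.85 (1.41 against -1.43) and the arterial endothelial list by -0.63 (-0.22 against 0.40). The mixed cluster with endothelial transcripts was part of these sums. In macrophage-like cells AA467197 differed by -6.52 (-1.46 against 5.06). In myogenic-like cells Xlr5a differed by 2.77 (1.03 against -1.74) and Ntm by 2.74 (1.49 against -1.26). Xlr5a and Ntm were among the 10 leading genes of the largest background-rich cluster. That cluster held 2087, 410, 861 and 3970 cells in the order of the libraries. Their ratios may therefore not be particular to endothelial- or myogenic-like cells. Technical measures went opposite ways too, in the order of the libraries. Background-rich clusters took 28.9%, 8.61%, 19.1% and 55.5% of the cells. Median mitochondrial shares were 6.48%, 4.28%, 5.62% and 7.86%. Cells with both Xist and Y-linked UMIs made up 12.5%, 4.65%, 4.71% and 14.7%. Median UMI counts and Malat1 were instead lower in both ischemic limbs. Library quality or handling cannot be told apart from genotype and limb in these 18 results.

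The first pattern weighed was that macrophage-like cells differed far less between the knockout limbs, with 36 genes at least 2-fold higher and 13 lower, than between the wild-type limbs, with 122 and 493. Within the resident-type cluster interferon genes had -0.31 in the knockout beside -0.35 in wild type and glycolysis 0.15 beside 0.48, but within the other main cluster they had 0.13 beside -1.02 and -0.38 beside 0.78. If the knockout muscle responded as wild type, an exchange of the 2 knockout libraries would give knockout control over knockout ischemic the wild-type change. With a weaker response it would not, so the test cannot decide on an exchange in that case. In knockout control over knockout ischemic, the 615 macrophage genes at least 2-fold apart between the wild-type limbs had a signed median of -0.15, against 1.17 in wild type. The 20 leading genes of the 2 clusters gained in the wild-type ischemic library decide nothing on an exchange, with a median of 0.21 there over members that went both ways (12 of 20 higher), nor on responding cells hidden among background-rich or doublet-called barcodes, because genes chosen from that library were lower in the knockout ischemic (-2.29) and in the wild-type control library (-1.78) alike, over all barcodes of 2500 UMIs or more. The effect of genotype could not be told apart from a difference between pools, with 1 pool per group. In the knockout the macrophage genes had a signed median of 0.15, with 69.3% in the wild-type direction. A general shift gives such a lean too. Of the 615 genes, 493 were lower in the wild-type ischemic limb, and the median log2 ratio of all genes in macrophage-like cells of the knockout limbs was -0.10. Hidden cells, a milder injury, 1 wrong limb label and an exchange with a weaker response stay open. Clusters leaned either way, 1 led by Slit2 with 216, 23, 219 and 25 cells and 1 led by Timp1 with 10, 475, 98 and 6 in the order of the libraries.

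The second pattern was the lower endothelial-like share in the knockout ischemic library. The higher UMI minimum of its barcodes did not by itself account for it. With a common minimum the log2 ratio over the knockout control limb was -1.39. That minimum still left 52.25% of the knockout ischemic cells in background-rich clusters, against 10.76% of the knockout control cells. It therefore cannot decide whether the calling of barcodes in the knockout ischemic library, 20000 in number, filled the denominator. Without background-rich clusters in the denominator the log2 ratio was -0.38, and with those clusters counted in their class -0.75. In the knockout ischemic library, barcodes with both Xist and Y-linked UMIs at 2000 UMIs made up 8.26% (7.71 to 8.83) of the background-rich clusters. They made up 0.784% (0.439 to 1.29) of endothelial-like cells, a ratio of 10.5. Such an excess was not particular to that library. It was 9.17% against 0.840% in wild-type control, 3.51% against 0.408% in wild-type ischemic and 4.26% against 0.502% in knockout control. A mixture of RNA from several cells is a candidate explanation for the background-rich barcodes, and thus for part of the lower share, while a loss of endothelial cells in that limb stays open.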

How the results depend on the processing

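No paired analysis was possible because each group was 1 library. Counting error was the only spread measured, and the spread between pools, which also limits what can be read, is not known. The cause of the moves below was not tested. The alternatives with a common UMI minimum, with background-rich clusters named or left out of the denominator, without the mixed pericyte-like cluster and with the capillary-like cluster alone were chosen after the data were seen. Of 162 alternative values of shares, mural ratios, gene counts and Tnfsf10, 101 stayed within the limits, 61 moved and 0 reversed, where only a value whose interval excluded 0 could count as reversed. The mural ratio (I), whose interval held 0, changed sign under 2 of them. Of 2154 for named genes, 739 moved and 10 reversed. Of 1192 for gene lists, 1084 kept their place, 60 were stronger, 45 weaker and 3 reversed. Of 416 for other class shares, 245 moved. Tnfsf10 stayed lower in the knockout throughout, from -0.65 to -0.48 in the control limb and from -0.53 to -0.26 in the ischemic limb.

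The letters W, K, C and I stand for the comparisons in the order of the report. The endothelial-like share had a log2 ratio of 0.74 (W) and -1.12 (I) with a strict cell filter. In cells with Xist alone it was 0.98 (W), 1.28 (C) and -0.95 (I), and with Y-linked UMIs alone 0.26, -0.97, 0.33 and -0.90. It was 0.75 (W) and -1.39 (K) with a common UMI minimum, and 0.65, -0.75, 0.71 and -0.69 with background-rich clusters in their class. Without those clusters in the denominator it was 0.48, -0.38, 0.65 and -0.22. With a marker score per cell it was -0.90 (K) and -0.98 (I), with Leiden resolution 0.5 -1.06 (K) and -1.12 (I), and without immune and erythroid cells in the denominator -1.37 (K) and -1.45 (I).

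The mural ratio was -0.10 (I) with Xist alone, -0.52 (C) with Y-linked UMIs alone, and -0.56 (W), 1.26 (K) and 1.01 (I) with background-rich clusters in their class. It was -1.05, 1.54, -0.999 and 1.59 with a marker score per cell, -0.11 (W) and -0.34 (C) without the mixed pericyte-like cluster, and 0.23 (K) and -0.14 (I) with Leiden resolution 0.5.

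Endothelial genes at least 2-fold apart numbered 56, 25, 40 and 47. With Xist alone there were 125 (W), 111 (C) and 93 (I), and with Y-linked UMIs alone 89 (W) and 99 (I). With a marker score per cell there were 85 (W), 174 (K) and 204 (I), and with cells thinned to equal depth 102 (W). A pseudocount of 5 gave 37, 13, 20 and 31, a floor of 50 CPM gave 26, 11, 15 and 20, and no floor gave 197, 85, 133 and 192. Endothelial gene lists beyond the percentile limits numbered 21, and 33 with Xist alone. Tnfsf10 was -0.53 (I) with Xist alone.

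With Y-linked UMIs alone the dissociation and immediate early list in endothelial-like cells reversed to -0.17 (K) and 0.49 (C), and the p53 and apoptosis list to 0.28 (C). With TMM factors Cdh5 reversed to 0.00958 and Pecam1 to 0.0200 (W). In the capillary-like cluster alone Tagln reversed to -0.0374 (W). With a marker score per cell, Aqp1 in fibroblast-like cells reversed to 0.21 (I), Cxcl14 to 1.37, C1qb to 0.90, Clu to 0.19 and Lyz2 to 0.31 in pericyte-like cells (I), and Alcam in myogenic-like cells to -0.95 (C). With doublet calls kept, Alcam reversed to -0.47 (C).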

Other observations

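Of the tests in this part, the one in cells of equal UMI range was chosen before its result was seen, and the others after. Several transcripts of injured muscle were far higher in the wild-type ischemic library than in the other 3. Over all barcodes of 2500 UMIs or more, Spp1 stood at 4.94, 127, 17.6 and 12.6 CPM in the wild-type control, wild-type ischemic, knockout control and knockout ischemic libraries. Tnc stood at 19.5, 199, 27.8 and 17.5 CPM, Timp1 at 17.8, 292, 60.4 and 13.8 CPM, and Trem2 at 7.95, 50.6, 5.76 and 9.16 CPM. Gpnmb differed less, at 18.1, 25.2, 23.7 and 23.3 CPM. The embryonic myosin gene Myh3 stood at 0.101, 6.99, 0.0207 and 0.0440 CPM, and Myog, which was high in both wild-type libraries, at 12.7, 25.6, 0.114 and 1.41 CPM. A cluster led by Timp1, Tnc, Cthrc1 and Lox held 10, 475, 98 and 6 cells. Lymphatic-like cells made up 0.365%, 0.684%, 0.261% and 1.27% of the cells, at median depths of 13540, 8884, 21490 and 3147 UMIs. Pericyte-like cells had Tnfsf10 at 51.1, 48.6, 36.7 and 33.2 CPM. A pericyte-like cluster with endothelial markers at 68.1% of the endothelial-like level held most of that class. It had 432 of 568, 351 of 520, 232 of 338 and 229 of 303 pericyte-like cells. Pecam1 in the class stood at 696, 634, 715 and 653 CPM, against 1111, 1015, 1142 and 1068 CPM in endothelial-like cells. The pericyte-like Tnfsf10 level thus cannot be told apart from endothelial transcripts.

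Another pattern was higher glycolysis genes in the wild-type ischemic limb in all 5 classes examined. The medians were 0.60 in endothelial-, 0.33 in fibroblast-, 0.51 in pericyte-, 0.99 in macrophage- and 0.89 in myogenic-like cells. The pericyte-like class is not independent of the endothelial-like one, given its mixed cluster. In endothelial-like cells, the only class tested for depth and scaling, the median was 0.60 in cells of 5000 to 10000 UMIs as well (1139 and 1020 cells) and 0.75 with TMM factors, which argues against both there. The myofibre markers used for naming did not rise with it, with a highest median of -0.0657 over the 5 classes. Those markers were taken without an expression floor. They include Acta1 and Mylpf of the leading genes of the cluster found in that library alone, but not Tnnt2, Actc1 or Myh3. RNA carried over from such cells was therefore tested only in part and stays open. The library also stood apart in Malat1, at 21892, 11898, 30376 and 22996 CPM in the order above, and in the median mitochondrial share, at 6.48%, 4.28%, 5.62% and 7.86%. Neither a difference in RNA quality or handling nor a metabolic change was tested, and both stay open.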
